A study of Mus musculus with 4 samples.

How the data were processed

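Gene expression was measured in caecal tissue of mice on Affymetrix arrays, with 1 array for each of 4 groups. Per the labels, all mice were C57Bl/6, were 21 weeks old and ate a diet depleted of n-3 polyunsaturated fatty acids. They were either wild type (WT) or lacked apolipoprotein E (apoE KO), and each genotype was kept with or without prebiotics at 250 mg per mouse per day over the last 15 days. RNA of 6 mice per group was pooled before labelling, the mice having been chosen on RNA quality, and 100 ng of RNA was labelled per array. Each group is therefore 1 pooled sample, and the spread between mice cannot be seen in these data.

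The deposited values are on a log2 scale: per the submitters' processing notes, Affymetrix Expression Console and RMA were used, with no version or setting named. RMA subtracts background, brings the arrays to a common distribution and summarises the probes of a probe set, which compresses differences close to background. The log base was taken from RMA and is not stated elsewhere in the sources used here. A genome build was not given in the sources used here, so no coordinates are printed. The number of arrays limits the precision.

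The table held 41345 probe sets. The annotation gave 1 gene symbol for 23521 of them, several for 1814 and none for 16010, which are unnamed here. The probe sets with 1 symbol covered 22180 genes, of which 1082 had more than 1 probe set. The probe set with the highest mean over the 4 arrays stood for its gene. A gene entered a comparison if its value reached the median of the probe sets with 1 symbol on at least 1 array of that comparison. This left 13083 genes for the models over 4 arrays. The current symbols were looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, which held 99.2% of the identifiers and changed 0 symbols; this table also gave the order of genes along the chromosome of Apoe.

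The labels of the WT arrays contradict each other. For each of the 2 WT arrays, 3 fields (title, source name and treatment) give a diet, and 1 field (description) gives the opposite diet. The arrays were grouped by title, and no label was inferred from the values. Counts of genes that need the diet of a WT array were also computed with the WT pair exchanged. The labels of the KO arrays do not conflict, and the mean of the WT arrays does not depend on the conflict.

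The genotype comparison set 2 KO arrays against 2 WT arrays (2 residual degrees of freedom), in limma 3.58.1 under R 4.3.3 with lmFit and eBayes with a trend. Its error term holds the difference between diets. The prebiotic comparison over both genotypes used the terms genotype and prebiotic on the 4 arrays, with 1 residual degree of freedom, which is the interaction. Tests in limma were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. These p-values measure only the spread between the 4 pooled samples. Comparisons of 1 array with 1 array have no test: genes at 2-fold or more were counted and are described as higher or lower.

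Before the data were examined, 21 pathway lists and 20 lists of cell type markers were fixed, and 40 of the 41 had at least 3 members that passed the filter and were scored; the other had 1. A list was described by its median log2 difference and the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. Such a percentile describes these arrays and is not a test. For genotype, limma's camera was also run with a preset correlation between genes of 0.01 and with an estimated correlation. The rule for naming genes was fixed at the same time. It took Apoe, the 12 largest differences each way for prebiotics in KO and for genotype, the 5 largest called each way for prebiotics over both genotypes, the 6 largest each way for the WT pair, the 4 largest each way for the difference of prebiotic effects, and up to 4 members of each list described. By the form of their names, predicted genes, microRNAs, small nucleolar RNAs with names in Snor, olfactory and vomeronasal receptors and immunoglobulin or T cell receptor segments were counted and not named. The small nucleolar RNA Rnu3a has another form of name and stayed in.

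The tests were checked on simulated data with 200 changed genes among 13083. For genotype, 83% of simulated 2-fold changes and 100% of 4-fold changes were recovered, and 15 unchanged genes were called. For prebiotics over both genotypes the figures were 81%, 100% and 19. The simulated noise was independent between genes, and the 200 changed genes ease the Benjamini-Hochberg limit. The recovered shares therefore do not give the power of the real comparisons, where Apoe itself was not called for genotype. A simulated list of 15 genes shifted by 0.3 on the log2 scale stood at percentile 99.9.

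Alternatives were no expression filter, a filter at the 75th percentile, the mean over a gene's probe sets, cyclic loess, centring each array on its median, a 1.5-fold threshold, eBayes without a trend, diet as a block, each array left out in turn, the mean in place of the list median, and the exchanged WT pair. After seeing the data, 5 further alternatives and 2 further marker lists were added. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.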

Results

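Caecal gene expression was compared between WT and apoE KO mice, with and without dietary prebiotics, on a background diet depleted of n-3 polyunsaturated fatty acids. Apolipoprotein E is the ligand by which the liver clears lipoprotein remnants, and prebiotics are carbohydrates that gut bacteria ferment. The study's title places the work in nutritional targeting of the gut microbiota in endothelial dysfunction. Each of the 4 groups was 1 array of RNA pooled from 6 mice, so no value below has a replicate of its own group. The median of all probe sets lay between 2.92 and 2.93 log2 units on the 4 arrays, and Pearson's r between arrays, across probe sets, lay between 0.984 and 0.988. The SD of the log2 difference between a pair of arrays ranged from 0.20 to 0.25.

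Apoe, the gene knocked out, had log2 values of 3.90 and 4.09 on the WT arrays titled without and with prebiotics. On the KO arrays without and with prebiotics it had 2.83 and 3.13, close to the array median. The KO mean was lower by a log2 difference of -1.02 (SE 0.16, limma adjusted p = 0.78 over all genes, 0.0024 adjusted over the list alone of 8 liver X receptor targets). Both KO arrays lay below both WT arrays, so its values follow the genotype labels. Whether the probe set lies in the deleted part of the gene is not known here.

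In KO mice, the pool given prebiotics had higher values than the pool without for some alpha-defensins and lysozyme 1, for a bile acid transporter and for a pair of heat shock genes. The alpha-defensins Defa21, Defa22 and Defa24, antimicrobial peptides of small intestinal Paneth cells, had log2 values of 8.18, 7.87 and 6.21 against 3.08, 2.84 and 2.68, which lie at about the array median and thus near background, so their folds are not well determined. Lysozyme 1 (Lyz1) had 6.02 against 3.75, also a low value. Reg3b, a lectin that kills bacteria, was 10.0-fold higher, from a value of 3.18, and Slc10a2, which takes up bile acids, was 6.42-fold higher. Lower on the prebiotic array were, among others, Ang4, an antimicrobial ribonuclease (log2 difference -1.71), and Cd79a and Cd79b, the signalling chains of the B cell receptor (-1.36 and -1.19, down to values of 3.16 and 2.47). In all, 58 of 12216 genes were at least 2-fold higher on the KO prebiotic array and 17 at least 2-fold lower.

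Other genes among the 12 highest were Hspa1b and Hspa1a, inducible heat shock proteins, with log2 differences of 3.01 and 2.19, and the gut peptide neurotensin (Nts) with 2.19. Naaladl1, a brush border peptidase, had 2.67, Clca4b 2.61 and Ms4a10 2.49. Also lower were Scgb2b20 at -1.49, the anion and drug exporter Abcc4 at -1.47, Syne1 at -1.29, the leukocyte phosphatase Ptprc (CD45) at -1.28, Cped1 at -1.21, H2-Q10 at -1.18, the carbonyl reductase Cbr3 at -1.11, Ms4a4d at -1.08 and lipoprotein lipase (Lpl) at -1.03. An array compared also lay near background for Reg3b, Clca4b, Naaladl1, Scgb2b20, Cd79a and Cd79b, so the sizes of these differences are approximate. Syne1 had 59 probe sets, and the mean over them gave -0.43. For Cped1, H2-Q10 and Lpl the mean over probe sets gave -0.58, -0.70 and -0.59. Alpha-defensin genes are near-identical copies, so the copy behind each signal is uncertain. Of 9 probe sets with a single alpha-defensin name, 4 were at least 2-fold higher, as were 4 of 9 probe sets that name several genes including an alpha-defensin.

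Among the fixed lists, genes of bile acid handling were higher on the KO prebiotic array, with 8 of 9 measured members above 0, a median log2 difference of 0.67 and a percentile of 100 among matched random lists. Beside Slc10a2, the prostaglandin transporter Slco2a1 and the basolateral bile acid exporter subunit Slc51a each had 1.12. Fabp6 had 0.96, from a value of 2.66 near background, so its size is approximate. Antimicrobial peptides had a median of 0.52 (percentile 100), with 7 of 10 members higher, among them Saa3 at 1.39, and with Ang4 in the opposite direction. Markers of mature colonocytes were higher in 10 of 10 members (median 0.40, percentile 100), led by Car4 at 0.72 and Aqp8 at 0.67. Transport of short-chain fatty acids and ions had a median of 0.25 (percentile 100), led by the butyrate transporter Slc5a8 at 1.84. This list and the colonocyte list share Slc26a3, Car1, Car4, Aqp8 and Guca2a, so they are not separate findings. Enteroendocrine hormones had a median of 0.19 (percentile 98.2), with cholecystokinin (Cck) at 1.73 and proglucagon (Gcg) at 1.21 beside Nts. Immediate early and heat shock genes had a median of 0.36 (percentile 100), with the phosphatase Dusp1 at 0.99.

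B cell markers were lower on the KO prebiotic array in 8 of 8 measured members (median -0.44, percentile 0), with Ms4a1 (CD20) at -0.62 and Fcer2a at -0.47. All 8 lay near background on that array, so these sizes are approximate. MHC class II genes were lower in 7 of 8 (median -0.41, percentile 0), with H2-Eb1 at -0.51 and H2-Aa at -0.50. The T cell list did not stand as low (median -0.18, percentile 5.2), but its genes lay near background on both KO arrays. Fatty acid oxidation and ketogenesis were lower in 11 of 14 (median -0.29, percentile 0), among them Pdk4, which restrains glucose oxidation, at -0.89, and the peroxisomal enzyme Ehhadh at -0.85. Proliferation genes were lower in 19 of 23 (median -0.17, percentile 0.040), smooth muscle markers in 10 of 12 (median -0.19, percentile 0.13) and endothelial markers in 8 of 12 (median -0.20, percentile 0.10). The nitric oxide and arginine list had a median of -0.05 (percentile 17.2). With 1 array per group these differences have no replicate check.

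In the WT pair, the array titled with prebiotics was compared with the array titled without. The values are given by array, because the descriptions give these arrays the opposite diets. Slc10a2 was 6.17-fold higher on the array titled with prebiotics, Slc3a1, a transporter of cystine and basic amino acids, 5.74-fold, Reg3b 5.57-fold, Slc5a8 4.12-fold, Nts 3.98-fold and the intestinal alkaline phosphatase Alpi 3.57-fold. Lower on it were the small nucleolar RNA Rnu3a (log2 difference -2.40), the lipoprotein lipase inhibitor Angptl4 (-2.02), haem oxygenase 1 (Hmox1, -1.96, down to a value of 3.11 near background), Abcc4 (-1.78), Cbr3 (-1.59) and Pdk4 (-1.54). Of 12223 genes, 41 were at least 2-fold higher on the array titled with prebiotics and 22 at least 2-fold lower.

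By list, antimicrobial peptides were higher on the WT array titled with prebiotics in 6 of 8 members (median 0.74, percentile 100), including Reg3g at 1.83 and Duox2 at 0.86. Colonocyte markers (median 0.26, percentile 99.8), short-chain fatty acid and ion transport (median 0.26, percentile 100), macrophage markers (median 0.28, percentile 99.9, with Mrc1 at 1.32) and fibroblast and matrix genes (median 0.24, percentile 99.6, with Col1a1 at 1.30) were also higher. Fatty acid oxidation was lower in 13 of 14 members (median -0.42, percentile 0), with Acot1 at -1.39 and Ehhadh at -1.38. Adipocyte markers (median -0.39, percentile 0), led by Fabp4 at -1.39, and smooth muscle markers in 12 of 12 members (median -0.26, percentile 0), led by Synpo2 at -0.88, were lower. B cell markers did not stand apart (median -0.03, percentile 29.1). With the descriptions in place of the titles, each of these signs turns for a reading by diet.

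**Figure D1:**
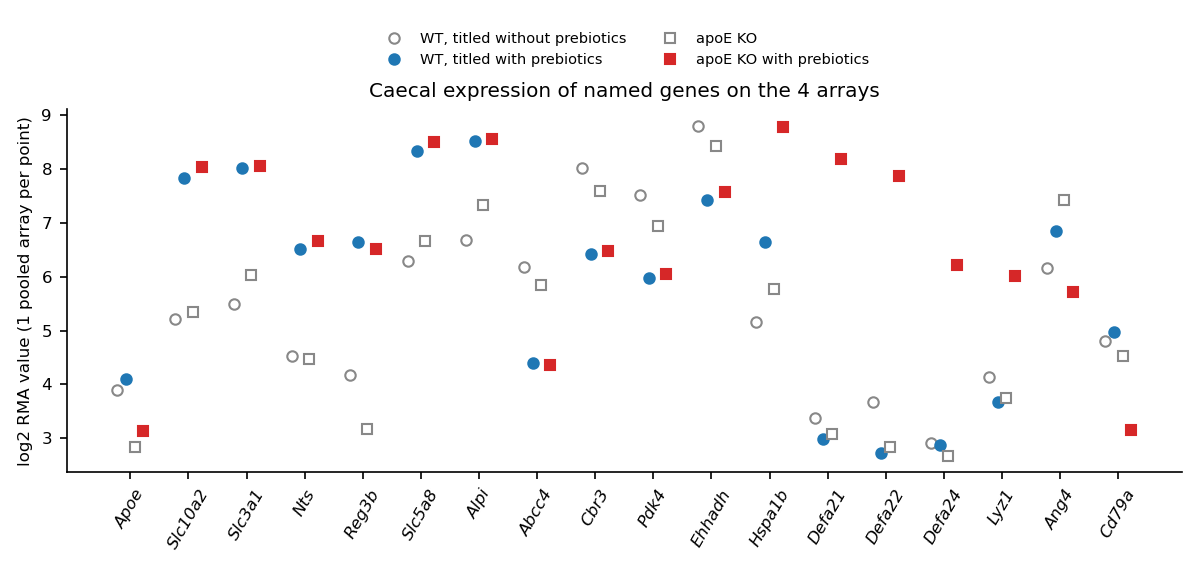
Log2 RMA values (vertical axis) of 18 named genes (horizontal axis) on the 4 arrays, each point 1 array of RNA pooled from 6 mice, with circles for WT, squares for apoE KO and filled symbols for arrays titled with prebiotics. Slc10a2 lay at 7.84 and 8.03 on the arrays titled with prebiotics against 5.21 and 5.34 on the others, while Defa21 reached 8.18 on the KO prebiotic array and lay between 2.98 and 3.37 elsewhere.

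Over both genotypes, with WT grouped by title, Reg3b rose with prebiotics by a log2 difference of 2.90 (SE 0.19, limma adjusted p = 0.00021), Slc10a2 by 2.65 (SE 0.11, limma adjusted p = 2.3e-05), Slc3a1 by 2.27, Hspa1b by 2.25 and Nts by 2.09. The largest falls were those of Abcc4 (-1.62, SE 0.14, limma adjusted p = 0.0011), Cbr3 (-1.35), Pdk4 (-1.21), Syne1 (-1.14) and Ehhadh (-1.12). In all, 130 genes were called higher and 34 lower by limma among 13083, and 1799 had an unadjusted p under 0.05. With the WT pair exchanged, limma called 0 genes in either direction and 170 had an unadjusted p under 0.05, so the calls in this comparison rest on the titles. Of the 164 genes called as titled, 79 had the opposite sign with the pair exchanged. The other 85 kept their sign without being called, such as Reg3b at 0.42 and Hspa1b at 0.77. Under the exchange, a gene that changed the same way in both pairs keeps its sign only if it changed more in KO. The 85 kept signs therefore do not show that these differences hold under either labelling.

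The counts adjusted over the list alone that follow rest on the titles too: with the WT pair exchanged, a run chosen after seeing the data, 0 genes were higher and 1 lower over all lists, Ang4 at -1.19. Of 10 colonocyte markers 6 rose and 0 fell in limma, with 10 called when adjusted over the list alone, and the chloride exchanger Slc26a3 (0.58) and the carbonic anhydrase Car4 (0.59) among them. Of 18 genes of short-chain fatty acid and ion transport 5 rose, Slc5a8 (1.94), the sodium exchanger Slc9a3 (0.50), Slc26a3, Car4 and Guca2a (0.25), with 9 higher and 1 lower when adjusted over the list alone. Slc26a3, Car4 and Guca2a are also among the colonocyte markers counted above. Of 10 antimicrobial genes 4 rose, Reg3b, Reg3g (1.53), Saa3 (1.10) and Duox2 (0.72), and 4 were higher and 1 lower when adjusted over the list alone. Of 10 members of the bile acid list 3 rose, Slc10a2, Slc51a (1.01) and the prostaglandin transporter Slco2a1 (0.83), with 4 higher and 1 lower when adjusted over the list alone. Among enteroendocrine hormones 3 of 15 rose, Nts, Gcg (1.44) and Cck (1.22), with 5 called when adjusted over the list alone. Hspa1b, Hspa1a (1.82) and Dusp1 (0.78) rose among 16 immediate early and heat shock genes, with 5 called when adjusted over the list alone. Of 15 mucus and goblet cell genes the mucins Muc3 (0.35) and Muc13 (0.27) rose, with 3 higher and 3 lower when adjusted over the list alone. Of 11 genes of nitric oxide and arginine 0 were called, also when adjusted over the list alone. Guca2a, Duox2 and Hadha were chosen after their values were seen.

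On the lower side, 4 of 14 genes of fatty acid oxidation fell, Pdk4, Ehhadh, Acot1 (-0.99) and the mitochondrial enzyme Hadha (-0.39), with 11 called when adjusted over the list alone. Fabp4 (-1.09) and Lpl (-0.87) fell among 9 adipocyte markers, 2 also when adjusted over the list alone. Myh11 (-0.41), Myl9 (-0.45) and Synpo2 (-0.78) fell among 12 smooth muscle markers, with 5 called when adjusted over the list alone. Of the other markers of cell types in the gut wall, fibroblast and matrix genes had a median of 0.24 (percentile 99.8), with Col1a1 (1.19) called among 12 and 5 higher and 1 lower when adjusted over the list alone. General epithelial markers had a median of 0.07 (percentile 70.7), with 0 of 10 called and 1 higher when adjusted over the list alone. Of the list members named here, Ceacam20, a colonocyte marker with 0.66 (limma adjusted p = 0.024), lies near Apoe. Its prebiotic difference is taken within each genotype, so a genotype difference near Apoe does not enter it. Without the trend in eBayes the counts were 21 higher and 4 lower. The fatty acid oxidation, adipocyte and smooth muscle genes named above were not among these 4. Without the expression filter the counts were 68 and 17, and with the mean over probe sets Syne1 had -0.44 and was not called.

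**Figure D2:**
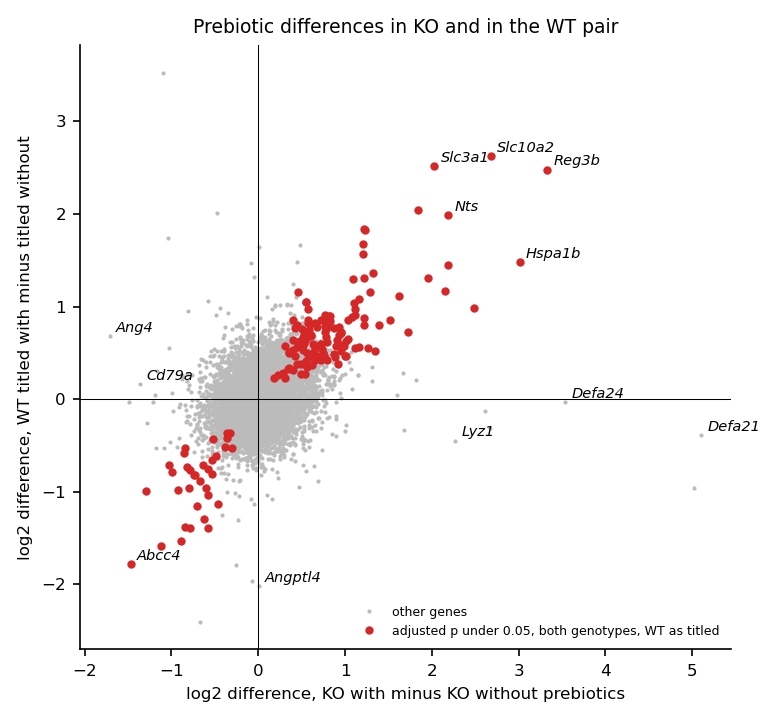
Log2 difference between the KO arrays (horizontal axis, with minus without prebiotics) against the log2 difference between the WT arrays (vertical axis, titled with minus titled without) for 13083 genes, with the genes called over both genotypes in red. Slc10a2 lay at 2.68 and 2.62, whereas Defa21 lay at 5.10 in KO and -0.39 in the WT pair.

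The KO and WT pairs share no array. Of 11356 genes measured in both, 57 were 2-fold higher in KO with prebiotics and 41 on the WT array titled with them, and 20 were in both sets against 0.206 expected for independent sets. Across these genes Pearson's r between the differences was 0.33 and Spearman's rho 0.29, and with the WT pair exchanged r was -0.33. Genes are not independent replicates, so no p is given. The same 2-fold limit put 2 genes lower in both pairs (Abcc4 and Cbr3), against 0.031 expected. As many, 2, were lower in KO and higher on the WT array titled with prebiotics, against 0.058 expected: the immunoglobulin light chain segments Igkv8-30 and Igkv9-120, chosen after their values were seen. In the remaining direction the count was 0, against 0.11 expected.

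The genotype comparison, KO against WT over both diets, gave 0 genes called by limma in either direction among 13083, while 430 had an unadjusted p under 0.05. The genes below were therefore ranked by size and did not pass. Highest on the KO arrays were Ms4a10 (log2 difference 2.80, SE 0.72), Defa21 (2.45), Defa22 (2.15), Igsf23 (1.73, SE 0.24), Defa24 (1.56), Hspa1a (1.55), Mypop (1.40, SE 0.15), Hspa1b (1.37), the clock repressor Nr1d2 (1.15), the chaperone Hsph1 (1.03), the hedgehog-binding protein Hhip (1.01) and Pla2g10os (0.99). The sizes and order of the alpha-defensins are not well determined, because their values on the other 3 arrays lie near background, as do those of Ms4a10 and Mypop on a WT array. The values of Defa21, Defa22, Defa24 and Hspa1b rest on the KO prebiotic array: without it they were -0.10, -0.36, -0.21 and -0.13. Without that array Hspa1a was 0.46 and Ms4a10 1.55, and without the WT array titled without prebiotics Nr1d2 was 0.75, Hspa1a 0.83 and Hspa1b 0.63. For a gene, leaving out the other array of the same genotype moves the value as far the other way.

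Lowest on the KO arrays were Rnu3a (-1.76), the glutamine transporter Slc1a5 (-1.20, SE 0.13), the acyl-CoA thioesterase Acot1 (-1.08), Cd79a (-1.05), Apoe, Sprr1a (-0.90), Angptl4 (-0.85), Ceacam20 (-0.83), Sfn (-0.79), Pisd-ps3 (-0.77), the insulin-degrading enzyme Ide (-0.76) and the urokinase receptor Plaur (-0.75). Without the WT array titled without prebiotics Angptl4 was 0.16, Acot1 -0.38 and Rnu3a -0.56. Without the WT array titled with prebiotics Sprr1a was -0.49 and Ceacam20 -0.45, and without the KO array kept without prebiotics Ceacam20 was -0.53. Without the KO prebiotic array Cd79a was -0.37. Slc1a5, Cd79a, Ceacam20, Plaur, Mypop and Igsf23 lie within 150 measured genes of Apoe on the same chromosome. With diet as a block (1 residual degree of freedom) limma called 8 genes higher and 4 lower, and 0 in either direction with the WT pair exchanged (247 at an unadjusted p under 0.05), so these calls rest on the titles. The 8 were Igsf23, Mypop, Ms4a10, Hspa1a, Hsph1, Dcn, Cnn1 and Slc9a3, and the 4 were Slc1a5, Apoe, Ceacam20 and Ide; Dcn, Cnn1 and Slc9a3 were chosen after their values were seen. Without the KO array kept without prebiotics limma called 4 genes higher, Defa21, Defa22, Defa24 and Ms4a10.

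By list, fibroblast and matrix genes were higher on the KO arrays in 12 of 12 members (median 0.34, percentile 100), with decorin (Dcn) at 0.77 and Col6a1 at 0.65, and smooth muscle markers in 12 of 12 (median 0.28, percentile 100), with Cnn1 at 0.64. Macrophage markers were higher in 12 of 14 (median 0.24, percentile 100), with Mrc1 at 0.99 and C1qb at 0.74. Proliferation genes were lower in 21 of 23 (median -0.19, percentile 0), with Cdc20 at -0.45. B cell markers were lower in 10 of 10 (median -0.31, percentile 0), with Fcmr at -0.56 and Cd22 at -0.51 beside Cd79a. Except for Cd79a, these B cell markers lay under 4 log2 units on every array, many of them near background, so the sizes are approximate. Cholesterol synthesis and uptake was lower in 13 of 17 members (median -0.13, percentile 0.010) and synthesis of polyunsaturated fatty acids and lipogenesis in 7 of 9 (median -0.16, percentile 0.020, with Fads2 at -0.30).

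The median of each of these 7 lists moved by over 1.5 times with 1 array left out, in runs chosen after seeing the data. Without the KO prebiotic array the B cell median was -0.09 with 7 of 10 members lower (Fcmr -0.36, Cd79a -0.37), the proliferation median -0.07 and that of polyunsaturated fatty acid synthesis -0.06 (-0.25 without the KO array kept without prebiotics). Without the WT array titled without prebiotics the fibroblast median was 0.18, the macrophage median 0.15, Mrc1 0.32, C1qb 0.34 and the smooth muscle median 0.46, and the proliferation and polyunsaturated fatty acid medians were -0.12 and -0.11. Without the WT array titled with prebiotics the smooth muscle median was 0.15, Cnn1 0.43, Cdc20 -0.27 and Fads2 -0.14. Without the KO array kept without prebiotics the smooth muscle median was 0.16, the cholesterol median -0.07 and Col6a1 0.33, while the B cell median was -0.53. These lists kept the sign of their medians with any 1 array left out.

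In limma's camera with a preset correlation of 0.01, adjusted over the 40 lists, the fibroblast and proliferation lists had adjusted p = 9.2e-07, smooth muscle 3.2e-06, B cells 5.5e-06 and macrophages 0.00085. Cholesterol synthesis had 0.012, germinal centre and Paneth-like markers 0.021 each and polyunsaturated fatty acid synthesis 0.024. With an estimated correlation each of these 9 lists had adjusted p = 0.82, so 0 of them was called. Without the KO prebiotic array the Paneth-like median was 0.08 in place of 0.28 (Defa24 -0.21, Lyz1 -0.16), and the germinal centre median was -0.09 in place of -0.16 without the WT array titled without prebiotics. Adjusted over the list alone, limma called Dcn and Dpt (0.61) higher among fibroblast genes, Hsph1 among heat shock genes and Apoe lower in the liver X receptor list.

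**Figure D3:**
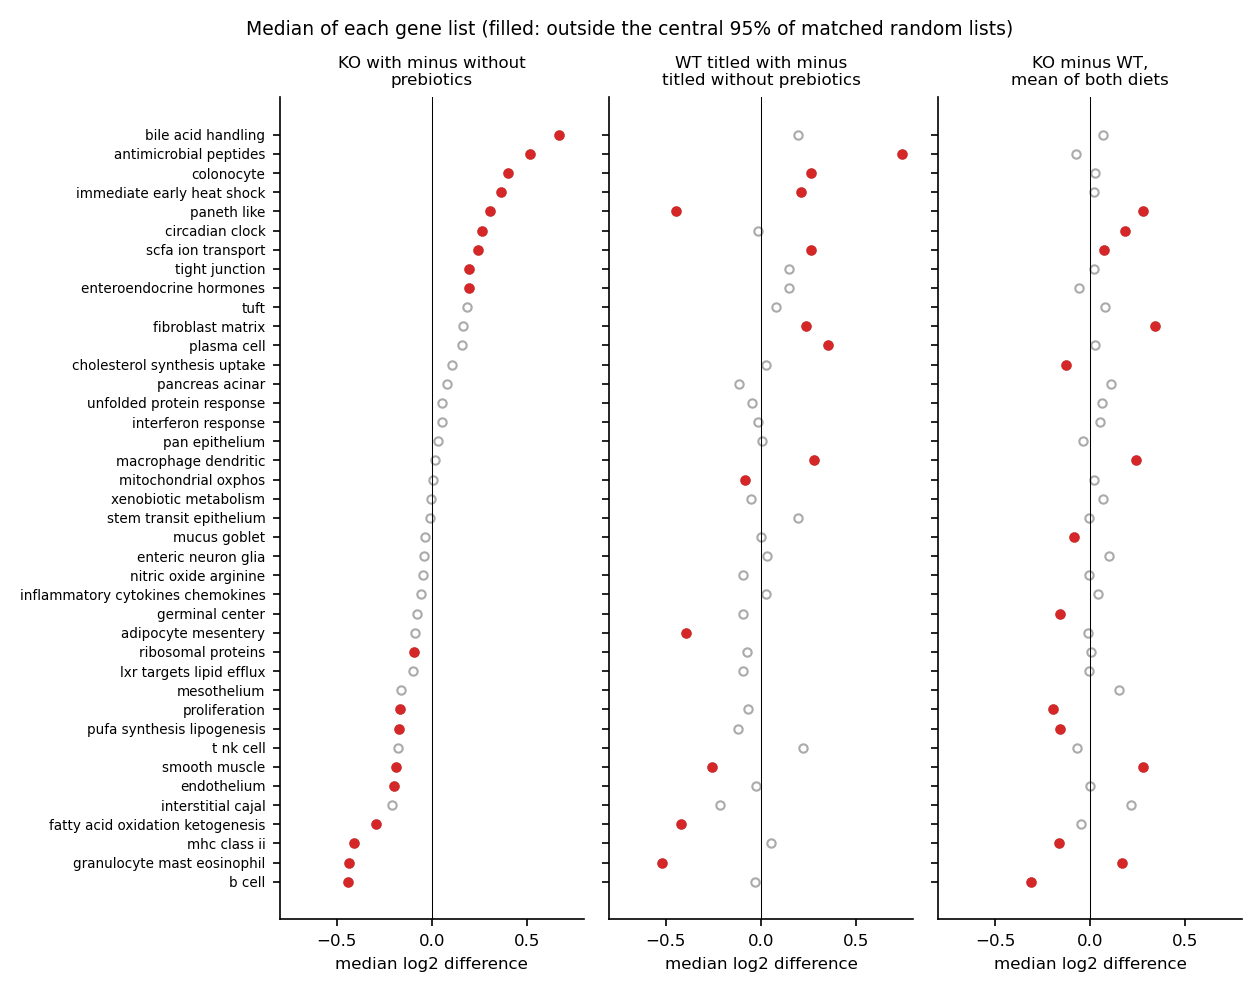
Median log2 difference (horizontal axes) of the 40 gene lists (vertical axis) for KO with minus without prebiotics, the WT array titled with minus titled without prebiotics, and KO minus WT over both diets, with filled points outside the central 95% of matched random lists. The mesothelium list has no point for the WT pair, where too few of its members passed the filter. B cell markers lay at -0.44, -0.03 and -0.31, and fatty acid oxidation at -0.29, -0.42 and -0.05.

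Within each diet, with WT grouped by title, 26 genes were at least 2-fold higher and 16 lower on the KO than on the WT array without prebiotics, and 18 and 16 with prebiotics. With the WT pair exchanged the counts were 27 and 48 without prebiotics and 84 and 24 with them. The prebiotic difference in KO exceeded that in WT by 2-fold or more for 47 genes and lay as far below it for 45, and for 281 and 98 with the WT pair exchanged. Among the named genes the excess was highest for Naaladl1 (2.98) and the alpha-defensins Defa22 (5.98), Defa21 (5.49) and Defa24 (3.57), whose sizes and order are not well determined because the other 3 arrays lie near background. It was lowest for Ang4 (-2.39), the acute phase gene Serpina3n (-1.64), the neutrophil marker Ly6g (-1.56, near background on 3 arrays) and Cd79a (-1.52). The median absolute log2 distance from the WT mean was 0.122 for the KO array and 0.126 for the KO prebiotic array, with 32 and 40 genes at 2-fold or more. None of these counts has a test, because each group is 1 array.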

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

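All tests in this part, and the limit used to select genes for it, were chosen after the results were seen. Of the 49 genes that the naming rule took by size, 7 had prebiotic differences in opposite directions in KO and the WT pair as titled. Each did so by more than the SD between its pair of arrays over all genes (0.23 and 0.22), as did 421 of all 13083 genes. The naming rule took genes with large differences, also between these effects, so 7 of 49 cannot be compared with 421 of 13083. The difference between the effects was not tested, because each group is 1 array, and with the WT pair exchanged the WT sign turns. KO minus WT effects on the log2 scale were 5.98 for Defa22, 5.49 for Defa21, 2.71 for Lyz1 and 2.98 for Naaladl1, which were higher with prebiotics in KO and lower on the WT array titled with them, the defensins from values near background on the other 3 arrays. They were -2.39 for Ang4, -1.64 for Serpina3n and -0.67 for Pisd-ps3, which ran the other way. The list of Paneth-like markers differed by 0.75 between the pairs, with a median of 0.31 over 6 members in KO (percentile 99.6) and -0.45 over the 3 measured in the WT pair (percentile 0.17). Over the same 6 members the median difference of effects was 0.51.

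Defa21, Defa22, Defa24, Defa35 and Lyz1 were at least 2-fold higher on the KO prebiotic array than on the KO array, by a log2 difference of 1.66 (Defa35, named after its value was seen) or more. The test run first came out in favour of ileal tissue in that pool. It used 18 ileal enterocyte genes, 11 of them at 4 log2 units or more on another array and so also seen in caecum. Fabp2 was at 11.66 and Apob at 10.01 on the KO prebiotic array. Their medians lay above each other array, the smallest 0.14 at percentile 99.9 of matched random lists. The 10 Paneth markers beyond the pattern (4 also seen in caecum) had -0.0301 at percentile 50.6. The ileal list was also higher on the WT array titled with prebiotics than on the other WT array (median 0.17, percentile 97.8). There Defa21, Defa22, Defa24 and Lyz1 were lower and Defa35 was higher by 0.28, so this list can shift without the pattern. A second test, chosen after the first had gone that way, pointed against ileal tissue: 11 ileal genes under 4 on the other arrays had a median rise of 0.12 (SD 0.35, highest Fabp6 at 0.96), and 9 such Paneth markers had -0.11 (SD 0.22, highest Itln1 at 0.46), while Ang4, well above background, was lower by a difference of -1.71. A rise from near background can be seen, as for the alpha-defensins, and the 11 ileal genes did not rise as far (highest level 3.73). Ileal tissue stays open because the tests point opposite ways, and how far such tissue would raise these probe sets is not known here. More Paneth cells also stay open, although both tests point against them. The 9 markers of the second test lie near background. The spread between genes in the first (SD 0.63) is wider than the shift tested, but it includes the fall of Ang4, which itself runs against more Paneth cells. A response of Paneth cells to prebiotics without more cells, or material from 1 of the 6 mice pooled, was not tested and may also account for the pattern.

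Among probe sets outside the gene comparisons, because they carry no gene name or several, 327 of 8319 above the expression limit were at least 2-fold higher on the KO prebiotic array than on the KO array and 212 at least 2-fold lower. In the WT pair the counts were 246 and 226.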

How the results depend on the processing

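Of the counts recomputed under the alternatives, 85 stayed within 1.5 times the value reported and 25 moved further. Of the list medians 967 stayed, 93 moved and 6 reversed, where stayed means a shift smaller than the spread of matched random lists. Of the named genes 470 stayed, 4 moved, 13 passed the threshold where they had not, 9 no longer passed and 10 reversed. Between a pair of arrays, a gene stayed if it shifted by less than their SD. In limma it stayed if its sign and its side of the threshold were kept, whatever its size. Rnu3a for genotype thus stayed at -0.56 in place of -1.76, without the WT array titled without prebiotics. At 1.5-fold, prebiotics in KO gave 321 genes higher and 141 lower, the WT pair 253 and 136, KO minus WT 159 and 132 without and 151 and 90 with prebiotics, and the difference of effects 410 and 334, because the limit is lower. With the WT pair exchanged, KO minus WT without prebiotics gave 48 lower, with prebiotics 84 higher, the difference of effects 281 higher and 98 lower, and prebiotics over both genotypes 0 and 0. In that setting Abcc4 was 0.16, Cbr3 0.24, Ehhadh 0.27, Pdk4 0.32 and Slc3a1 -0.25.

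For prebiotics over both genotypes, no expression filter gave 68 genes higher and 17 lower, centring on the median 204 and 66, and eBayes without a trend 21 and 4, the 4 being Abcc4, Cbr3, Syne1 and Cd36, the last chosen after its value was seen. For genotype, diet as a block gave 8 and 4. With each array left out in turn, where the lone array of a genotype is assumed to vary like the other genotype, genotype gave 0 to 4 genes higher and 0 lower. Over these settings the genotype difference ranged from -1.86 to 0.16 for Angptl4, -0.10 to 5.0005 for Defa21, -0.36 to 4.66 for Defa22, -0.21 to 3.33 for Defa24 and -0.13 to 2.88 for Hspa1b. Without the expression filter the granulocyte and mast cell list had 0.0588 for prebiotics in KO, in place of -0.44 (percentile 0.060), and 0.0119 over both genotypes, in place of -0.41 (percentile 0). Except where stated, the cause was not tested. The alternatives chosen after seeing the data left 53 higher and 16 lower for prebiotics in KO without defensin and small intestinal genes, 0 and 0 for genotype without the neighbours of Apoe, and 0 and 0 for genotype with diet as a block and the WT pair exchanged. Also chosen then, genotype list medians with each array left out ranged from -0.051 to 0.4686 for granulocytes and mast cells, -0.2192 to 0.0184 for MHC class II and -0.0404 to 0.2106 for short-chain fatty acid and ion transport. No paired analysis was possible because the labels give no animal, batch or replicate number shared between groups; the diet block is a fit by group. Signals close to background, such as T cell markers near 3 log2 units, limit what can be seen there.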

Other observations

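Of the tests in this part, those on the neighbours of Apoe were chosen after the result was seen, and the T cell test was written before its result was known, except that its margin, the SD of the genes, was set afterwards. On the KO arrays the repressor Nr1d2 was higher by a log2 difference of 1.15 and the output gene Dbp by 0.77, and Ciart by 0.48, while the activator Arntl was lower by a difference of -0.49 and Nfil3 by -0.55. Ciart on the WT arrays and Nfil3 on the KO arrays included values near background, so these sizes are approximate. These 5 of 14 measured clock genes were called by limma when adjusted over the list alone (adjusted p = 0.019, 0.019, 0.032, 0.021 and 0.021), and 0 when adjusted over all genes. The list median was 0.18 (percentile 100 among matched random lists) and 0.04 without the KO prebiotic array. Nr1d2 was 0.75 without the WT array titled without prebiotics. On this list camera gave adjusted p = 0.16 with a preset and 0.84 with an estimated correlation. With 10 members higher and 4 lower, the median and camera depend on how many genes of each direction were listed. They therefore do not measure a pattern in which members move in opposite directions. In KO the prebiotic array also stood higher for the list (median 0.26, percentile 99.8, Per1 at 0.63), and in the WT pair it did not stand apart (median -0.01, percentile 32.1). The hour of tissue collection is not given in the sources used here.

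Genotype differences were frequent among neighbours of Apoe. Of 284 measured neighbours, 11 (3.87%) differed by 1.5-fold or more with both KO arrays on the same side of both WT arrays, against 66 of 12798 other genes (0.516%), an odds ratio of 7.77 (Fisher's exact test, two-sided, p = 7.8e-07); chance puts 33.3% of genes on separate sides and 30.2% were. This is consistent with a chromosome segment of another strain left around the knocked-out gene, a candidate explanation that these labels do not settle. Sequence variants under the probes would lower the KO signal. For the 8 genes that were lower (72.7% of the 11, among them Slc1a5, Cd79a and Ceacam20), such variants cannot be told apart from real differences. The other 3, Tmem160 (0.72), Mypop and Igsf23, were higher, which a lowered signal would not give. An effect of apolipoprotein E itself on these 11 neighbours stays open, as untested.

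Cd79a, Cd79b and Ms4a1 were lower on the KO prebiotic array than on the KO array, by differences of -1.36, -1.19 and -0.62, down to values near background. Cd79a is also a neighbour of Apoe, but both arrays are KO, so a genotype difference near Apoe does not enter this comparison. Less lymphoid tissue in the KO prebiotic pool may account for these lower values. The T cell list had a median of -0.18 (SD 0.21 over 6 genes), above the 2.5th percentile of matched random lists at -0.22, by less than that SD. Its genes lay near background on both KO arrays, where a fall can hardly be seen. The test therefore cannot count against less lymphoid tissue, which stays open. Other immune genes went both ways. MHC class II (-0.41, percentile 0, 7 of 8 lower) and Ptprc (-1.28) were also low. The germinal centre list (-0.08, percentile 15.1) and plasma cell list (0.16, percentile 87.2) were not. Granulocyte and mast cell markers were low (-0.44, percentile 0.060) on only 4 measured of 14 members, and had 0.0588 without the expression filter. A prebiotic effect on B cells is also open, as untested.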
